A study of Arabidopsis thaliana with 8 samples.

How the data were processed

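Transcript levels were measured with Affymetrix ATH1 arrays in 4 groups of Arabidopsis thaliana shoot samples, 2 arrays per group. RNA was prepared with a Qiagen RNeasy kit and hybridised by the manufacturer's standard procedure, per the labels' protocols. The deposited table holds linear probe set intensity values for 22810 probe sets on 8 arrays. Probe set intensity was summarised with MAS5, per the submitters' processing notes. The median of every array in the deposited intensity table was exactly 50. No label states the step that set it, and detection calls were not used here.

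The 2% trimmed means of the deposited arrays ranged from 117 to 175, a 1.5-fold difference that exceeded the limit of 1.2 set in advance, so each array was multiplied to the median trimmed mean of 132.7 (factors 0.757 to 1.14). The 64 control probe sets were left out. A pseudocount of 7.7, the value at percentile 20 of the scaled table, was added before taking log2. A probe set was kept if it lay above the percentile 30 value of its array on at least 2 arrays.

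Gene names came from a platform annotation table, which lists 14016 of the probe sets, and from the RefSeq gene table of assembly TAIR10.1, used for names only. Of the listed probe sets, 503 match several genes and were left out, and 13436 of the 13513 with 1 gene matched the RefSeq table. The 8730 probe sets missing from the annotation table stayed unnamed. They include those of many well-known shoot genes, so that STM, KNAT1, CUC2, TCP4, GRF5, LHCB3, SPL9, SAG12, FLC and other genes chosen in advance have no value. For each gene the probe set with the highest mean was used, which gave 9905 genes.

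Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend, two-sided), with all 8 arrays in 1 fit and 4 residual degrees of freedom beside 6.21 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. The comparisons were older with younger apices, expanding leaves with older apices, mature with expanding leaves, and mature leaves with younger apices. An F test covered all 4 groups. Changes and folds are on the scale of log2(value + 7.7) and shrink for low signals. Changes are log2 differences with their standard error (SE), and group means are given with the SD.

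Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. A list needed 5 tested members. Of 30 lists fixed before the data were examined, 6 reached that size, because few members had names. After the annotation table was read, but before gene values were looked at, 29 lists were added, of which 28 reached it, so that 34 lists were tested. The lists fixed before the data were examined are named so in the text.

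Genes were named by a rule set before the data were examined: per comparison, the 10 largest increases and 10 largest decreases among genes past the threshold whose groups did not overlap, up to 3 passing members of every list (or the member with the lowest p), and, for genes that rose or fell in stage order, the 5 largest of each. The text gives a part of these. FMA, AOP3, SWEET1, SWEET10 and ORA47 are among the genes also given in comparisons where the rule did not name them. AOP3, GSTU20, UGT74B1 and AT2G31790 were followed as a set of glucosinolate genes only after their values were seen.

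The steps were tested on 1 random draw of simulated data with the 9905 genes and the spread of these arrays. For mature against expanding leaves, 30% of genes changed 2-fold and 92% of genes changed by 2 log2 units were recovered, and 16 of 145 calls were false. A single draw does not fix these shares. The simulated noise was independent between genes, with 1 spread per gene for all groups. Only a small part of the genes was changed, while 21.4% passed in this comparison of the data. The shares therefore need not hold for these arrays. Alternatives covered the scaling (equal medians as deposited, quantile), pseudocount, filter, intensity trend, robust fit, the use of only the groups compared, replicate number as a block, the choice of probe sets, a 2-fold minimum and leaving out each array. Equal medians for the list tests were added after the data were seen. Leaving out an array also lowers the degrees of freedom and, in a compared group, tends to raise the SE. A call lost in this way can therefore reflect lost power and not what that array measured.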

Results

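Transcript levels were followed through a series of shoot tissues of Arabidopsis thaliana, accession Landsberg erecta, from young vegetative apices to fully expanded leaves. Plants grew on soil in short days of 10 h light at 20 °C. The groups were younger apices (Apex_5DAS), older apices from day 14 after sowing (Apex_14DAS), the expanding leaves 1 and 2 of the same day (EL_14DAS) and mature leaves from day 35 (ML_35DAS), with 2 arrays each. The sample titles place the younger apices at day 5 and the source names at day 7, so they are called younger apices here. No label says that the 2 arrays of a group come from separate plants. The p-values therefore measure only the spread between these arrays, and the small number of arrays limits the precision.

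The 2 mature-leaf arrays resembled each other most, with a Pearson r of 0.978 across the 9905 genes, which are not independent replicates. The r was 0.960 for older apices, 0.951 for expanding leaves and 0.908 for younger apices, where 12.7% of genes differed more than 2-fold between the 2 arrays. Apex_5DAS replicate 1 stood apart in its control probe sets. Its 25S ribosomal RNA signal was 193, against 0.961 to 21.3 on the other arrays, and its dap spike-in signal was 1.41, against 24.3 to 108. The ratio of the 3' to the 5' actin probe set was 2.39 on that array, 2.47 and 2.59 on the mature-leaf arrays, and 1.4 to 1.73 on the remaining arrays. The same ratio for GAPDH did not set these 3 arrays apart: it was 1.19 on Apex_5DAS replicate 1 and 1.21 on replicate 2, 1.04 and 1.01 on the mature-leaf arrays, and 0.843 to 1.15 on the other 4.

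Whether the vegetative apex changes with age was addressed by comparing older with younger apices. BCAT4, a methionine aminotransferase that starts the side-chain elongation of aliphatic glucosinolates, was 49.5-fold higher in older apices, with a log2 intensity of 10.21 ± 0.87 against 4.58 ± 0.65 (SD, n = 2; adjusted p = 0.0022). AT5G55450, a member of the lipid-transfer protein family, rose from 3.23 ± 0.08, near the pseudocount, to 8.56 ± 0.07 (adjusted p = 0.0011; by 7.08 with the pseudocount at percentile 5 and by 3.77 at percentile 40), and AT5G59330 of the same family rose 17.7-fold (adjusted p = 0.0017). In the other direction, the jasmonate-regulated JRG21 was 7.03-fold lower (adjusted p = 0.0047). AT5G44440, which encodes a berberine-bridge-type oxidase, fell from 7.40 ± 1.47 to 3.29 ± 0.17, near the pseudocount (adjusted p = 0.0087), so its fold is not fixed (-5.69 with the pseudocount at percentile 5 and -2.71 at percentile 40). Its call was lost without either Apex_14DAS array (adjusted p up to 0.065) and with only the 2 groups compared (0.063). Other sizes moved too. BCAT4 rose by 4.76 with the pseudocount at percentile 40, by 5.02 without Apex_14DAS replicate 1 and by 6.25 without replicate 2, against 5.63. JRG21 changed by -3.45 and -1.92 with the pseudocount at percentile 5 and 40, against -2.81. Of the 9905 genes, 117 were higher and 137 lower in older apices, and 102 and 131 of these differed at least 2-fold.

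AOP3, which modifies the side chain, rose by 2.84 ± 0.33 (SE), the glucosyltransferase UGT74B1 by 1.80 ± 0.36 and the glucosyltransferase AT2G31790 by 1.67 ± 0.30. SPCH, which starts the stomatal lineage, rose by 1.44 ± 0.28 (adjusted p = 0.03), and the flowering regulator AGL24 rose by 1.67 ± 0.36 (adjusted p = 0.044). Both calls were lost when any single array other than Apex_5DAS replicate 2 was left out (adjusted p up to 0.19 and 0.26). The chitinase-family gene AT2G43590 rose from 3.21 and 3.12 on the younger-apex arrays, near the pseudocount, to 6.56 ± 0.36 (adjusted p = 0.0017), and AT3G16670, a relative of the pollen Ole e 1 proteins, was 12.6-fold higher (adjusted p = 0.00068). Among late embryogenesis abundant genes, LEA4-5 fell by 2.41 ± 0.41, a call lost without Apex_5DAS replicate 1 or any array of older apices or mature leaves (adjusted p up to 0.14). The sugar transporters SWEET11 and SWEET2 were 5.96-fold and 3.27-fold lower, while the other 12 of 14 tested SWEET genes did not pass. IAA29, an auxin-response repressor, was 4.47-fold lower (adjusted p = 0.019). Of the genes named in this paragraph only AOP3, AT2G43590 and AT3G16670 passed without each array in turn. The call of AGL24 was lost with equal array medians (adjusted p = 0.052). Those of SPCH and AGL24 were lost with the pseudocount at percentile 5 (adjusted p = 0.064 and 0.076). Without a filter the calls of both, SWEET11, UGT74B1, AT2G31790 and IAA29 were lost (adjusted p up to 0.07). With only the 2 groups compared these were lost too, as were SWEET2 and LEA4-5 (adjusted p up to 0.16). Without Apex_5DAS replicates 1 and 2, SWEET11 changed by -1.55 and -3.61, against -2.57, and without Apex_14DAS replicate 2 AOP3 rose by 3.43. With the pseudocount at percentile 5 and 40 the changes were 5.20 and 1.99 for AT2G43590, 2.44 and 0.92 for AGL24 and -4.32 and -1.19 for LEA4-5. At percentile 40 they were 3 for AT3G16670 and -1.48 for IAA29.

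Cell wall loosening genes were tested as a list. Of 32 expansins, xyloglucan enzymes and endoglucanases, 2 fell and 30 did not pass, with a median change of -0.34 (camera adjusted p = 0.0042). With an estimated correlation the adjusted p = 0.61. EXPA8 was 6.02-fold and XTH32 2.36-fold lower. Both calls were lost without at least 4 of the arrays and without the intensity trend (adjusted p up to 0.16). Of the 9 expansins, a list fixed before the data were examined, 1 fell among all genes and 3 fell adjusted over the list alone (median -0.53, camera adjusted p = 0.018). That call, with an adjusted p = 0.61 with an estimated correlation, was lost without either Apex_5DAS array (adjusted p up to 0.097). The 19 mitosis and cytokinesis genes were higher as a group, all above the all-gene median, with a median of 0.64 and no single gene past the threshold (camera adjusted p = 0.00076). With an estimated correlation the adjusted p = 0.61, and without Apex_5DAS replicate 1 the camera adjusted p was 0.056.

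Plastid transcripts set the younger apices apart, but through 1 array. The 41 plastid-encoded photosynthesis genes had a median of -1.43 in older against younger apices (camera adjusted p = 1.7e-09), although none passed alone. With an estimated correlation the adjusted p = 0.62. Apex_5DAS replicate 1, the array with the high ribosomal RNA signal, had a median of 8.18 for these genes and replicate 2 had 5.03. Without replicate 1 the median relative to all genes was -0.06 (adjusted p = 0.63). The 9 nuclear photosynthesis genes fixed before the data were examined included 1 that fell, LHCB4.2, and 5 that fell adjusted over the list alone. Their median was -0.63 (camera adjusted p = 7e-04, and adjusted p = 0.61 with an estimated correlation), and the call was lost without the same array (adjusted p = 0.066).

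Of the 34 lists tested between the apices, 11 passed with camera, none with an estimated correlation and none with fry. In the longer list of 25 nuclear photosynthesis genes the median change was -0.44 and 1 gene fell (camera adjusted p = 0.02, and adjusted p = 0.70 with an estimated correlation). The median level of this list went the other way, from 9.91 and 9.66 on the younger-apex arrays to 9.97 and 10.38 on the older-apex arrays. The call was lost with quantile normalization (adjusted p = 0.17) and without Apex_5DAS replicate 1 or Apex_14DAS replicate 1 (adjusted p up to 0.72). The 16 plastid genes of gene expression were lower, at a median of -1.14 (camera adjusted p = 0.00076, and adjusted p = 0.62 with an estimated correlation), and without Apex_5DAS replicate 1 the adjusted p was 0.98. The 121 ribosomal protein genes were slightly higher, at 0.21, with 1 that rose (camera adjusted p = 0.00076, and adjusted p = 0.67 with an estimated correlation), a call lost without Apex_5DAS replicate 2 or Apex_14DAS replicate 2 (adjusted p up to 0.52). Of 9 cold and dehydration genes 2 fell, LEA4-5 and COR47, at a median of -0.29 (camera adjusted p = 0.02, and adjusted p = 0.61 with an estimated correlation), and the call was lost without the same arrays (adjusted p up to 0.12). The medians of 6 RALF peptide genes and 12 tetraspanin genes were -0.62 and -0.72 with no gene past the threshold (camera adjusted p = 0.032 and 0.036, and adjusted p = 0.61 with an estimated correlation for both). The RALF call was lost without Apex_5DAS, Apex_14DAS, EL_14DAS or ML_35DAS replicate 1 (adjusted p up to 0.23), and the tetraspanin call without either Apex_5DAS array, Apex_14DAS replicate 2 or ML_35DAS replicate 2 (adjusted p up to 0.21). Of the other lists fixed before the data were examined, chlorophyll synthesis had 1 gene that rose, CHLI2, and 2 that rose adjusted over the list alone, and floral timing had 1, AGL24, in both counts, and neither list passed (camera adjusted p = 0.18 and 0.56).

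In all, 254 genes passed the threshold between the apices, and 1908 had an unadjusted p below 0.05. With equal array medians 75 were higher and 147 lower, and with quantile normalization 161 and 188. The groups did not overlap for 47.1% of genes, against 33.3% by chance. Here and below, 33.3% is an expected share and not a bound, since an effect on a whole array moves many genes together. Replicates differed most in younger apices (SD of the log2 difference 0.702) and least in mature leaves (0.387). The fit gives each gene 1 spread, which may therefore be too small for younger apices. Leaf arrays enter this comparison mainly through that spread. The count depended on single arrays: it was 91 without Apex_5DAS replicate 1, 1789 without its replicate 2, 27 and 35 without Apex_14DAS replicates 1 and 2, 166 without EL_14DAS replicate 2, and 52 and 50 without ML_35DAS replicates 1 and 2. Of the 41 genes named by rule that passed, 9 passed without each of the 8 arrays in turn, among them BCAT4, AOP3, AT5G55450, AT5G59330, AT2G43590, AT3G16670 and JRG21; the other 32 were lost without at least 1, including 22 without Apex_5DAS replicate 1, 29 and 30 without the Apex_14DAS replicates 1 and 2, 10 and 12 without the EL_14DAS replicates, and 29 without each ML_35DAS array.

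**Figure D1:**
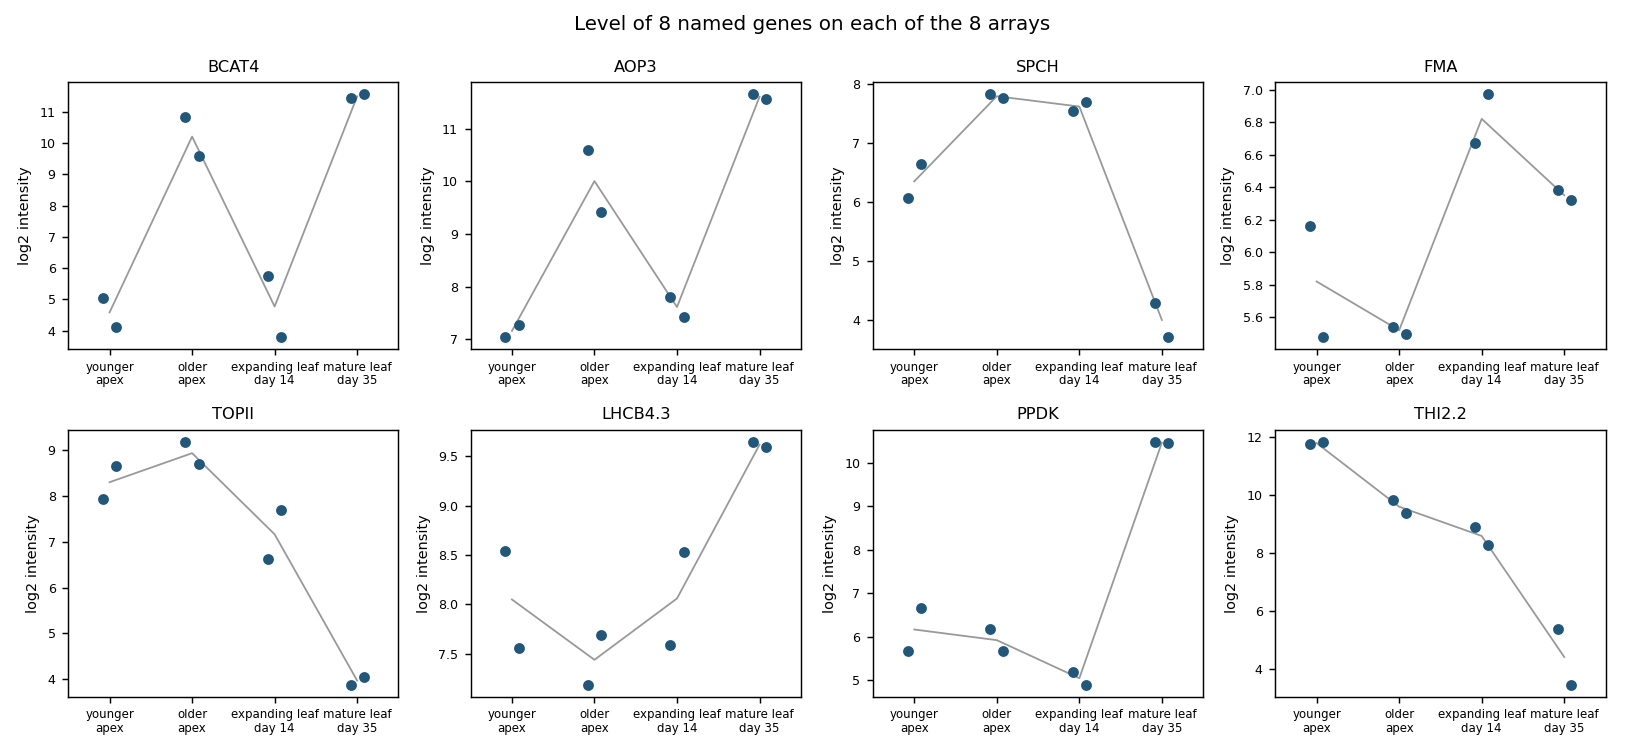
Log2 intensity of 8 named genes (vertical axis) in each of the 4 groups (horizontal axis), with each point 1 array and the line joining group means. BCAT4 and AOP3 were high in older apices and mature leaves and low in younger apices and expanding leaves, and SPCH and TOPII were lowest in mature leaves. For LHCB4.3 the 2 arrays lay apart in younger apices (8.54 and 7.56) and in expanding leaves (7.59 and 8.53).

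Expanding leaves were compared with apices of the same day to ask what separates a growing leaf from the apex. Among the largest falls in the leaves were 3 genes of the lipid-transfer family, which was not tested as a list. AT5G59330 was 56.1-fold lower in expanding leaves, with 3.83 ± 0.52 against 9.64 ± 0.22 (SD, n = 2; adjusted p = 6.9e-05), AT4G22490 was 50.5-fold lower and AT5G01870 was 47.6-fold lower, but AT5G55450 of the same family was at 9.02 ± 1.35 in expanding leaves and 8.56 ± 0.07 in older apices. These folds and their ranking hold for the pseudocount of 7.7 only: with it at percentile 5 and 40 the changes were -6.78 and -4.57 for AT5G59330, -5.96 and -5.03 for AT4G22490 and -5.98 and -4.80 for AT5G01870. GH3.3, which conjugates auxin to amino acids, fell from 7.77 ± 0.03 to 3.34 ± 0.30, near the pseudocount (adjusted p = 2.8e-05), so its fold is not fixed (-6.00 with the pseudocount at percentile 5 and -2.99 at percentile 40). The fold of GH3.17, of the same family, also depends on the pseudocount (-4.59 and -2.72; adjusted p = 0.0021) and was -3.08 and -4.44 without the EL_14DAS replicates 1 and 2. The sucrose exporter SWEET11 rose 9.38-fold in the leaves, to 9.28 ± 0.41 (adjusted p = 0.007), and the sucrose phosphate synthase gene ATSPS4F rose from 4.56 and 3.16 on the older-apex arrays, the second near the pseudocount, to 7.09 and 6.63 (adjusted p = 0.0067). The rise of ATSPS4F was 4.12 and 1.95 with the other pseudocounts, and 3.73 and 2.31 without the Apex_14DAS replicates 1 and 2. Both rises were lost without Apex_14DAS replicate 2 or EL_14DAS replicate 1 (adjusted p up to 0.07).

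Of the 25 nuclear photosynthesis genes, 8 rose, none fell and 17 did not pass, with a median of 0.64 (camera adjusted p = 1.4e-08, and adjusted p = 0.55 with an estimated correlation). The chloroplast NADH dehydrogenase subunits NdhN and NdhL rose by 1.58 ± 0.27 and 1.46 ± 0.25, and the thylakoid protein CaS by 1.31 ± 0.20, and each of these calls was lost without at least 2 of the arrays (adjusted p up to 0.12). In the shorter list of 9, fixed before the data were examined, 2 rose over all genes and 6 rose adjusted over the list alone (camera adjusted p = 0.00022, and adjusted p = 0.55 with an estimated correlation), while with equal array medians none passed alone. The 41 plastid-encoded photosynthesis genes all lay above the all-gene median, at a median of 0.95, with none past the threshold alone (camera adjusted p = 0.00022, and adjusted p = 0.70 with an estimated correlation). Their median relative to all genes, 1.01, ran from 0.48 to 1.4 without 1 array (camera adjusted p up to 0.045), so its size rests on single arrays.

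Of 19 mitosis and cytokinesis genes, 6 fell, none rose and 13 did not pass, with a median of -0.92 (camera adjusted p = 6.4e-07, and adjusted p = 0.55 with an estimated correlation). The topoisomerase TOPII and the chromosome-associated 3xHMG-box2 were each 3.42-fold lower (adjusted p = 0.022 and 0.04), the kinase AUR2 was 2.96-fold lower and the checkpoint gene BUBR1 was 3.12-fold lower. Of 8 core histone genes, 2 fell, HTB1 and HTB2 (median -0.77, camera adjusted p = 0.011, and adjusted p = 0.55 with an estimated correlation). That call was lost without Apex_14DAS replicate 2 (adjusted p = 0.065). Each of the 6 mitosis and histone genes named here was lost without at least 2 of the arrays (adjusted p up to 0.23). Without the intensity trend TOPII, 3xHMG-box2 and HTB1 were lost (adjusted p up to 0.081), and without a filter 3xHMG-box2 and BUBR1 (adjusted p up to 0.079). These last 2 were lost as well with the pseudocount at percentile 5 (adjusted p up to 0.061), and with equal medians HTB1 was lost (adjusted p = 0.071).

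Of the 5 anthocyanin genes in a list fixed before the data were examined, 2 fell over all genes and 4 fell adjusted over the list alone, with a median of -1.81 (camera adjusted p = 0.011, and adjusted p = 0.55 with an estimated correlation). DFR, dihydroflavonol reductase, was 10.5-fold lower and the glucosyltransferase AT4G14090 was 10.3-fold lower. The size of this difference rests on single arrays: the older-apex arrays had list medians of 8.63 and 6.03, and the relative median ran from -2.86 to -0.81 without 1 array. DFR was lost without EL_14DAS replicate 2 (adjusted p = 0.073), and AT4G14090 without that array, Apex_14DAS replicate 1 or either ML_35DAS array (adjusted p up to 0.17), and also without a filter, without the intensity trend or with the robust fit (up to 0.085). Without the Apex_14DAS replicates 1 and 2 DFR changed by -2.33 and -4.46 and AT4G14090 by -2.08 and -4.69. Without the EL_14DAS replicates AT4G14090 changed by -4.25 and -2.53. With the pseudocount at percentile 40 DFR changed by -2.80, and AT4G14090 by -4.50 and -2.35 at percentile 5 and 40. The longer flavonoid list of 7, with the same 2 falls, had a median of -1.54 (camera adjusted p = 0.024, and adjusted p = 0.55 with an estimated correlation). Its relative median ran from -2.15 to -0.63 without 1 array, so its size rests on single arrays too. The call was lost without either Apex_5DAS array, Apex_14DAS replicate 1 or EL_14DAS replicate 1. BCAT4 fell from 10.21 ± 0.87 in older apices to 5.74 and 3.80 on the expanding-leaf arrays (adjusted p = 0.0011), and AOP3 fell 5.25-fold (adjusted p = 0.0036). The size for BCAT4 rests on single arrays: -4.83 and -6.06 without the Apex_14DAS replicates 1 and 2, -6.43 and -4.46 without the EL_14DAS replicates, and -4.59 with the pseudocount at percentile 40.

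NUB and PTL, which act in lateral organs, were 4.92-fold and 4.22-fold lower, while the abaxial-fate gene YAB5 was 2.04-fold higher; the other 16 of 19 tested leaf blade regulators did not pass (camera adjusted p = 0.16). FMA, which completes guard cell differentiation, rose by 1.30 ± 0.28 (adjusted p = 0.024). TRY, an inhibitor of trichome fate, was 2.16-fold higher, and SIM, a cell cycle inhibitor of trichomes, was 2.28-fold lower. NUB passed without each array in turn, but the calls of YAB5, FMA, TRY and SIM were lost when any single array of older apices, expanding leaves or mature leaves was left out (adjusted p up to 0.33). That of PTL was lost without Apex_14DAS replicate 2 or either EL_14DAS array (adjusted p up to 0.16). The beta-glucosidase PYK10 of endoplasmic reticulum bodies was 8.33-fold lower (adjusted p = 3e-04), and the peroxidase-family gene AT5G58390 was 21.7-fold lower (adjusted p = 2.8e-05). With the pseudocount at percentile 5 and 40 the changes were -5.23 and -3.31 for AT5G58390, -2.95 and -1.46 for NUB, and -3.06 and -1.14 for PTL, which lay near the pseudocount in expanding leaves (3.47 and 3.65). The calls of YAB5, FMA, TRY and SIM were also lost without a filter (adjusted p up to 0.09), and that of SIM with equal medians and quantile normalization (0.082 and 0.07). Of 9 expansins, EXPA9 rose and EXPA15 and EXPB3 fell, and both falls were lost with equal array medians and all 3 calls without at least 5 of the arrays (adjusted p up to 0.22). Adjusted over the list alone, 3 expansins rose and 3 fell. In all, 7 of the 34 lists passed with camera, none with an estimated correlation and none with fry.

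Between expanding leaves and older apices, 624 genes passed the threshold, 280 higher and 344 lower, and the groups did not overlap for 54.6% of genes, against 33.3% by chance. With equal array medians 343 were higher and 228 lower, so that 39.9% of the passing genes were lower in place of 55.1%. The count was 1222 and 1178 without the Apex_5DAS replicates 1 and 2, 185 and 95 without the Apex_14DAS replicates, 163 and 200 without the EL_14DAS replicates, and 275 and 274 without the ML_35DAS replicates. Of 70 genes named by rule that passed, 20 passed without each array in turn, among them AT5G59330, AT4G22490, AT5G01870, GH3.3, GH3.17, PYK10, BCAT4, AT5G58390 and NUB; 36 and 44 were lost without the Apex_14DAS replicates 1 and 2, 39 and 38 without the EL_14DAS replicates, and 32 without each ML_35DAS array.

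**Figure D2:**
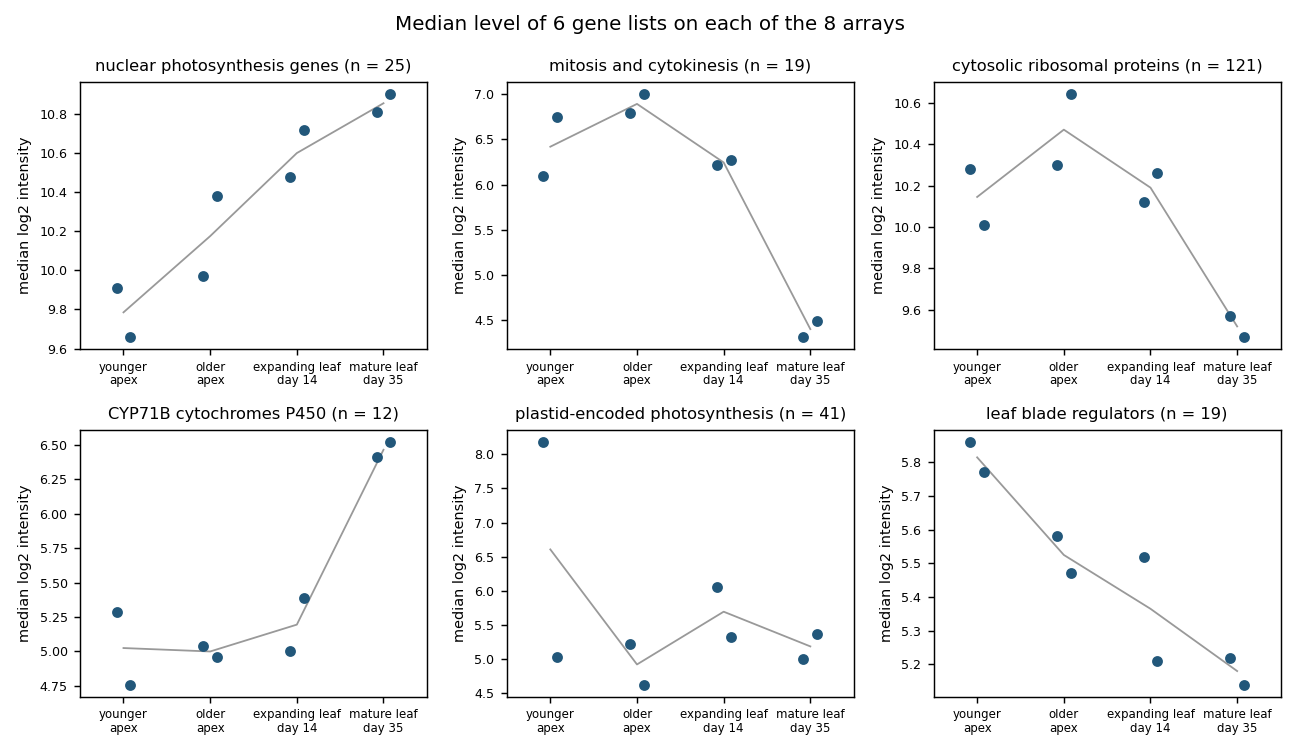
Median log2 intensity of 6 gene lists (vertical axis) on each array of the 4 groups (horizontal axis), with each point 1 array and the line joining group means. Mitosis and ribosomal protein genes were lowest and CYP71B genes highest on both mature-leaf arrays, and Apex_5DAS replicate 1 stood apart at 8.18 for the plastid-encoded genes.

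The comparison of mature with expanding leaves asked what changes as a leaf completes its growth. The labels give no leaf number for the mature leaves, and their plants were older. Leaf position and plant age therefore cannot be told apart from completed growth in these differences. Mature leaves had far more PPDK, pyruvate orthophosphate dikinase, at 10.46 ± 0.01 against 5.05 ± 0.20 (SD, n = 2; 42.6-fold, adjusted p = 1.7e-05), and FDH, formate dehydrogenase, was 13.7-fold higher (adjusted p = 1.7e-05). BCAT4 was 106-fold and AOP3 15.9-fold higher (adjusted p = 0.00016 for both). SPCH was 12.2-fold lower (adjusted p = 0.00012), and the mitotic genes 3xHMG-box2 and TOPII were 9.76-fold and 9.21-fold lower (adjusted p = 0.0011 and 0.00068). The thionin gene THI2.2 was 18.1-fold lower and PYK10 11.5-fold lower. The size for THI2.2, at 5.35 and 3.45 on the mature-leaf arrays, was -5.05 and -3.21 without the ML_35DAS replicates 1 and 2. That for BCAT4, at 5.74 and 3.80 on the expanding-leaf arrays, was 7.73 and 5.76 without the EL_14DAS replicates. With the pseudocount at percentile 5 and 40 the changes were -4.94 and -3.22 for THI2.2, -4.11 and -2.60 for PYK10, -4.35 and -2.58 for SPCH, and -3.92 and -2.21 for TOPII. At percentile 40 they were 4.75 for PPDK, 5.87 for BCAT4 and -2.53 for 3xHMG-box2.

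The median of all genes was -0.27 in mature against expanding leaves, and changes of lists are given relative to it. Of the 19 mitosis and cytokinesis genes, 13 fell, none rose and 6 did not pass (relative median -1.32, camera adjusted p = 4.7e-05, and adjusted p = 0.65 with an estimated correlation). AUR1, AUR2 and AUR3 were 5.61-fold, 6.12-fold and 4.48-fold lower, while with the pseudocount at percentile 40 AUR2 changed by -1.87 and AUR3 by -1.26 (-3.08 at percentile 5). Of 121 cytosolic ribosomal protein genes, 51 fell, 1 rose and 69 did not pass (relative median -0.36, camera adjusted p = 1e-05, and adjusted p = 0.65 with an estimated correlation), but with equal array medians 8 fell and the relative median was -0.32. AT3G14600 and AT3G44590 of this list were 3.01-fold and 2.95-fold lower. The mature-leaf arrays also had the highest actin 3' to 5' ratios, 2.47 and 2.59, against 1.47 and 1.73 on the expanding-leaf arrays, while the GAPDH ratios were 1.04 and 1.01 against 0.843 and 0.946, and in younger apices 1.19 and 1.21.

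Of the stomatal genes measured, too few to be tested as a list, SPCH fell as given above, its successor MUTE was 3.31-fold lower (adjusted p = 0.032) and STOMAGEN, a peptide that promotes stomata, was 2.19-fold lower (adjusted p = 0.016), while FMA changed by -0.47 and did not pass. The MUTE call was lost when any single array of older apices, expanding leaves or mature leaves was left out (adjusted p up to 0.18). That of STOMAGEN was lost without EL_14DAS replicate 2 or either ML_35DAS array (adjusted p up to 0.12), so only the fall of SPCH passed without each array. The MUTE call was also lost with quantile normalization, without a filter and with the pseudocount at percentile 5 (adjusted p up to 0.086), where the change was -2.74, against -0.89 at percentile 40. That of STOMAGEN was lost with equal medians (adjusted p = 0.1). Of 9 expansins, 5 fell over all genes and 6 fell and 1 rose adjusted over the list alone, led by EXPA15, 8.78-fold lower, and EXPB3, 3.81-fold lower, but the list did not pass (relative median -1.12, camera adjusted p = 0.096). The subtilase SBT1.3, the lipase-family gene AT5G45670 and the polygalacturonase-family gene AT1G10640 were 9.04-fold, 17.0-fold and 12.2-fold lower, and at percentile 40 the last 2 changed by -3.41 and -3.01. Of 19 leaf blade regulators, 1 rose, 5 fell and 13 did not pass, without a call (camera adjusted p = 0.43). NGA3, SPT and YAB3 were 3.54-fold, 3.12-fold and 2.53-fold lower, the first 2 lost without ML_35DAS replicate 1 and NGA3 also without EL_14DAS replicate 2 (adjusted p up to 0.13), and AGO7 was 2.54-fold higher (adjusted p = 0.048), a call lost without any array of older apices, expanding leaves or mature leaves (adjusted p up to 0.23), without a filter (0.082), with the replicate block (0.052) and with the pseudocount at percentile 40 (0.73, adjusted p = 0.062; 1.96 at percentile 5). At percentile 40 NGA3 and SPT changed by -1.21 and -1.03. The flowering repressor SMZ was 6.22-fold lower, and FD, a partner of florigen, was 2.71-fold lower, lost without EL_14DAS replicate 1 or either ML_35DAS array (adjusted p up to 0.086). AGL24 rose from 3.34 ± 0.04, near the pseudocount, in expanding leaves (adjusted p = 0.0049, and up to 0.057 without either mature-leaf array). The changes with the pseudocount at percentile 5 and 40 were 3.29 and 1.03 for AGL24 and -2.31 and -0.71 for FD, and at percentile 40 SMZ changed by -1.86. Of the 5 floral timing genes fixed before the data were examined, 1 rose and 2 fell over all genes, 1 rose and 3 fell adjusted over the list alone, and the list was not called (camera adjusted p = 0.53).

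Lists of chlorophyll synthesis and photosynthesis were tested separately. Of 5 chlorophyll synthesis genes fixed before the data were examined, 4 fell over all genes and 4 fell adjusted over the list alone, without a list call (relative median -0.89, camera adjusted p = 0.07); PORB was 3.19-fold, CHLI2 2.56-fold and HEMB1 2.23-fold lower. PORB was lost without ML_35DAS replicate 1 (adjusted p = 0.059) and HEMB1 without EL_14DAS replicate 2 or either ML_35DAS array (adjusted p up to 0.068) and with equal medians (0.075). Of the 25 nuclear photosynthesis genes, 2 rose, among them LHCB4.3 (2.94-fold, lost without EL_14DAS replicate 1 or either ML_35DAS array, adjusted p up to 0.12), 1 fell and 22 did not pass. Their relative median of 0.60 passed (camera adjusted p = 0.0066, and adjusted p = 0.65 with an estimated correlation), but it was 0.09 with quantile normalization (adjusted p = 0.70) and the call was lost without EL_14DAS replicate 1 (adjusted p = 0.05). In the shorter list of 9, fixed before the data were examined, none passed over all genes and none adjusted over the list alone. Its relative median of 0.67 passed (camera adjusted p = 0.033, and adjusted p = 0.68 with an estimated correlation), but not with quantile normalization (0.09, adjusted p = 0.97) or without EL_14DAS replicate 1 or ML_35DAS replicate 1 (adjusted p up to 0.1).

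Lists of cytochrome P450, autophagy, glutathione transferase, sugar transport, defence and senescence genes were also tested. Of 12 CYP71B cytochrome P450 genes, 7 rose and none fell (relative median 1.24, camera adjusted p = 0.00038, and adjusted p = 0.47 with an estimated correlation), with CYP71B36 4.87-fold and CYP71B26 4.82-fold higher, the first lost without EL_14DAS replicate 1 and the second without EL_14DAS replicate 2 or either ML_35DAS array (adjusted p up to 0.096). CYP71B36 rose by 3.26 and 1.34 with the pseudocount at percentile 5 and 40. Of 10 autophagy genes, 3 rose and none fell: APG8H, ATG8E and ATG8F (relative median 0.80, camera adjusted p = 0.0094, and adjusted p = 0.65 with an estimated correlation). The call of APG8H was lost without ML_35DAS replicate 1 (adjusted p = 0.072), that of ATG8E without each array of either leaf group (up to 0.23) and that of ATG8F without these or either older-apex array (up to 0.19). ATG8E and ATG8F were also lost with quantile normalization, without a filter and without the intensity trend (adjusted p up to 0.093). The list medians were 7.39 and 7.41 on the mature-leaf arrays and 7.04 and 6.73 on the expanding-leaf arrays, but 7.67 and 7.30 in younger apices, and the list was not called between the ends of the series (camera adjusted p = 0.35). Of 10 glutathione transferase genes, 2 rose (relative median 0.86, camera adjusted p = 0.021, and adjusted p = 0.65 with an estimated correlation), a call lost without EL_14DAS replicate 1 (adjusted p = 0.058). Of 14 SWEET sugar transporter genes, 3 rose, 2 fell and 9 did not pass, and the list was not called (camera adjusted p = 0.95). SWEET13, SWEET11 and SWEET17 were 7.59-fold, 3.73-fold and 3.09-fold higher, with the last 2 lost without 1 or more arrays (adjusted p up to 0.14). SWEET1 and SWEET10 fell by 1.23 and 1.25, SWEET10 to 3.07, near the pseudocount. Of 14 jasmonate and defence peptide genes, 3 rose and 2 fell, also without a call (camera adjusted p = 0.43): the defensin genes PDF1.2b and PDF1.2 were 10.8-fold and 4.17-fold higher and JMT, which methylates jasmonate, was 6.92-fold higher, while THI2.2 and ORA47 fell. At percentile 40 PDF1.2b, PDF1.2 and JMT rose by 2.64, 1.46 and 1.76, and JMT by 3.65 at percentile 5. The senescence list fixed before the data were examined had 1 gene that fell among 5, NOL, over all genes and adjusted over the list alone, lost without EL_14DAS replicate 2 or either ML_35DAS array (adjusted p up to 0.084) and with equal medians (0.058). The longer senescence list of 9 had 2 genes that rose, PPDK and the vacuolar protease gene GAMMA-VPE, 2 that fell, NOL and WRKY22, and 5 that did not pass, and was not called (camera adjusted p = 0.49). Of the 34 lists 7 passed with camera, none with an estimated correlation and 11 with fry.

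Between mature and expanding leaves, 2118 genes passed, 686 higher and 1432 lower, and the groups did not overlap for 70.5% of genes, against 33.3% by chance. The share of lower genes depended on the array scaling: 67.6% with equal trimmed means, 35.3% with equal medians and 51.9% with quantile normalization, with 1384 and 1370 of the genes passing in the same direction. The count rose when either Apex_5DAS array was left out, though neither belongs to the groups compared. It fell when any EL_14DAS or ML_35DAS array was left out. Of 98 genes named by rule that passed, 48 passed without each array in turn, among them PPDK, FDH, BCAT4, AOP3, SPCH, TOPII, THI2.2, SMZ, SWEET13, PDF1.2b and EXPA15; 27 and 35 were lost without the EL_14DAS replicates, 44 and 41 without the ML_35DAS replicates, and 8 without each Apex_14DAS array.

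**Figure D3:**
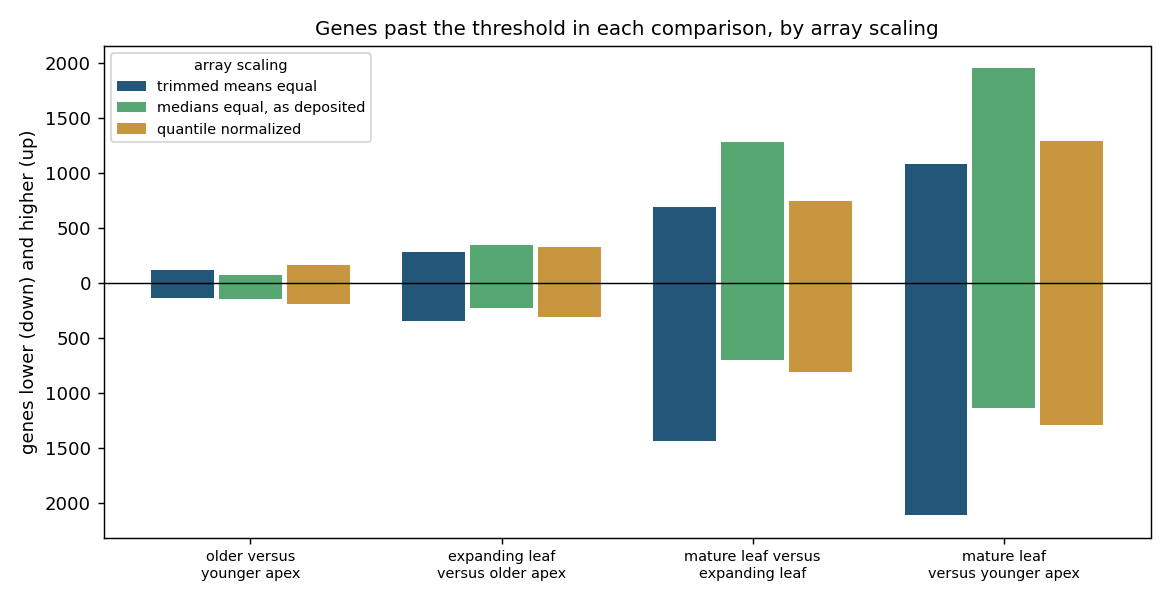
Number of genes past the threshold in each of the 4 comparisons (horizontal axis), higher above 0 and lower below 0 (vertical axis), under 3 array scalings. In mature against expanding leaves 1432 genes were lower with equal trimmed means, 698 with equal medians and 806 with quantile normalization.

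The ends of the series, mature leaves and younger apices, had the most genes past the threshold in the main fit. The order turned against mature and expanding leaves with only the 2 groups compared (2421 against 3095 genes). It also turned in the share of genes whose groups did not overlap (68.2% against 70.5%). THI2.2 was 166-fold lower in mature leaves, at 4.40 ± 1.34 against 11.78 ± 0.04 (SD, n = 2; adjusted p = 8.8e-06), and PYK10 was 150-fold lower (adjusted p = 4.1e-07). AT5G55450 rose from 3.23 ± 0.08 to 10.42 ± 0.20 (adjusted p = 8.8e-06), AT2G43590 from 3.21 and 3.12 on the younger-apex arrays to 9.77 ± 0.19 (adjusted p = 2.3e-06), and BCAT4 was 121-fold higher (adjusted p = 3.5e-05). The first 2 lay near the pseudocount in younger apices, so their fold is not fixed: AT5G55450 rose by 8.95 with the pseudocount at percentile 5 and by 5.57 at percentile 40, and AT2G43590 by 8.51 and 4.96. THI2.2 changed by -8.16 and -6.35 with these pseudocounts and PYK10 by -7.86 and -6.19. BCAT4 rose by 6.04 at percentile 40. Without the ML_35DAS replicates 1 and 2 THI2.2 changed by -8.25 and -6.41, the second less than the -7.23 of PYK10, so its place as the larger fall rests on 1 array. The median of all genes was -0.26.

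Of the 19 mitosis and cytokinesis genes, 14 fell and 5 did not pass (relative median -1.37, camera adjusted p = 1.5e-05, and adjusted p = 0.46 with an estimated correlation), and TOPII was 20.3-fold lower. Of 7 DNA replication genes, 4 fell, including PRL, the replication licensing factor, 5.68-fold lower (relative median -0.88, camera adjusted p = 0.032, and adjusted p = 0.46 with an estimated correlation), a call lost without Apex_5DAS replicate 2 (adjusted p = 0.13). Of 32 expansins, xyloglucan enzymes and endoglucanases, 15 fell and 2 rose (relative median -0.68, camera adjusted p = 0.0077, and adjusted p = 0.46 with an estimated correlation), with GH9B13 20.9-fold, EXPA15 14.1-fold and EXPB3 13.0-fold lower. Of the 9 expansins fixed before the data were examined, 4 fell over all genes and 5 fell adjusted over the list alone (camera adjusted p = 0.03, and adjusted p = 0.46 with an estimated correlation), a call lost without Apex_5DAS replicate 1 (adjusted p = 0.11). Of 19 leaf blade regulators, 10 fell and 9 did not pass, with NUB 5.74-fold, JAG 4.83-fold and LAS 3.82-fold lower (relative median -0.81, camera adjusted p = 0.022, and adjusted p = 0.46 with an estimated correlation), and this call was also lost without Apex_5DAS replicate 1 (adjusted p = 0.11). With the pseudocount at percentile 5 and 40 the changes were -5.10 and -3.25 for TOPII, -5.10 and -3.33 for GH9B13, -3.38 and -1.55 for NUB, -3.37 and -1.25 for JAG, and -2.67 and -1.14 for LAS.

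Of the 25 nuclear photosynthesis genes, 11 rose, none fell and 14 did not pass (relative median 0.92, camera adjusted p = 1.7e-06, and adjusted p = 0.46 with an estimated correlation). CaS and NdhL were each 2.92-fold higher and LHCB4.3 was 2.97-fold higher, the last lost without either ML_35DAS array (adjusted p up to 0.072). In the shorter list of 9, fixed before the data were examined, 1 rose over all genes and none adjusted over the list alone (relative median 0.68, camera adjusted p = 0.034, and adjusted p = 0.69 with an estimated correlation). That call was lost with quantile normalization (0.08, adjusted p = 0.74) and without Apex_5DAS replicate 2 or ML_35DAS replicate 1 (adjusted p up to 0.55). Of 12 CYP71B genes, 8 rose and 1 fell (camera adjusted p = 0.0032, and adjusted p = 0.46 with an estimated correlation). Of 10 glutathione transferase genes, 5 rose, led by GSTL3, 5.23-fold higher (camera adjusted p = 0.034, and adjusted p = 0.46 with an estimated correlation), a call lost without Apex_5DAS replicate 2 (adjusted p = 0.085) and with equal array medians (adjusted p = 0.068). Of 121 ribosomal protein genes, 45 fell and none rose (camera adjusted p = 0.0032, and adjusted p = 0.69 with an estimated correlation). With equal array medians 7 fell and 4 rose (adjusted p = 0.093), and without Apex_5DAS replicate 1 the adjusted p was 0.057. The mature-leaf arrays and Apex_5DAS replicate 1 shared high actin 3' to 5' ratios, 2.39 to 2.59, against 1.59 on the other younger-apex array, but their GAPDH ratios were 1.04, 1.01 and 1.19, against 1.21 on that array. Of the 5 anthocyanin genes fixed before the data were examined, 4 fell over all genes and 4 adjusted over the list alone, without a list call (camera adjusted p = 0.062). Of the 34 lists 10 passed with camera, none with an estimated correlation and 21 with fry.

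Between the ends of the series, 3196 genes passed, 1085 higher and 2111 lower, and the groups did not overlap for 68.2% of genes, against 33.3% by chance. The share of lower genes was 66.1%, 36.9% with equal medians and 50% with quantile normalization. The count was 1403 and 1565 without ML_35DAS replicates 1 and 2. Of 114 genes named by rule that passed, 83 passed without each array in turn, among them those with the largest changes given above; 9 and 11 were lost without the Apex_5DAS replicates, 27 and 23 without the ML_35DAS replicates, 5 without each Apex_14DAS array, and 3 and 4 without the EL_14DAS replicates.

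Of the 3196 genes that differed between the ends, 1016 (31.8%) had their group means in stage order, 323 rising and 693 falling. Genes picked for a difference between the ends tend to have the middle groups between them, so this share has no simple chance value. With the pseudocount of 7.7 the largest ordered rises were those of AT5G55450 (7.20), AT2G43590 (6.61), AT2G32160 (6.22), AT1G64360 (5.62) and AT1G35710, a receptor-like kinase gene (5.28). AT5G55450, AT2G43590 and AT1G64360 lay near the pseudocount in younger apices (3.23 and 3.11 for the first and last, against 2.94), so the size and ranking of these rises depend on it: AT1G64360 rose by 7.68 with the pseudocount at percentile 5 and by 3.95 at percentile 40, where AT2G32160 rose by 7.02 and 5.04. AT1G64360 was also not graded, at 3.25 in older apices, 3.28 in expanding leaves and 8.72 in mature leaves. With the same pseudocount the largest ordered falls were those of THI2.2 (-7.38), PYK10 (-7.23), the cytochrome P450 gene AT3G44970 (-6.60), AT4G29030 (-6.15) and GH3.17 (-5.42). Their size and ranking depend on it as well, as AT3G44970 and GH3.17 lay near it in mature leaves (3.31 and 3.38): with the pseudocount at percentile 5 and at percentile 40 the changes were -8.16 and -6.35 for THI2.2, -7.86 and -6.19 for PYK10, -8.25 and -5.04 for AT3G44970, -6.63 and -5.27 for AT4G29030, and -7.03 and -3.93 for GH3.17. Without ML_35DAS replicate 2 THI2.2 fell less (-6.41, and -8.25 without replicate 1), and AT3G44970 changed by -7.29 and -5.97 without the Apex_5DAS replicates 1 and 2. At percentile 40 AT1G35710 rose by 4.40. With equal medians 644 genes rose and 391 fell in order. By the F test 3504 genes differed among the 4 groups. Without ML_35DAS replicate 1 the count of ordered genes was 572 and that of the F test 1483, and without replicate 2 they were 590 and 1608.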

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

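Among the values in this part, only the list tests with equal array medians were chosen after the data were seen. All counts of changed genes between groups stayed within 1.5 times their value under quantile normalization, equal array medians, both other pseudocounts, the filter at percentile 50, the robust fit, averaged probe sets, the probe sets left after dropping ambiguous types, and the 2-fold minimum. Using replicate number as a block gave 260, 651, 2168 and 3292 genes. These are for older against younger apices, expanding leaves against older apices, mature against expanding leaves and the ends of the series. The main fit pairs no arrays. Replicate differences correlated at 0.312 between older apices and expanding leaves, both of day 14, and at 0.126 between younger apices and expanding leaves. The other pairs of groups lay between -0.094 and 0.0431. Pairing of replicates at day 14 therefore stays open. The block was 1 term shared by all 4 groups, so the counts with it do not test a pairing limited to day 14. Testing all non-control probe sets, which tests more features, gave 630, 1334, 3926 and 6001, 6738 by the F test and 1918 in stage order. Without a filter the first 2 counts were 90 and 354, and without the intensity trend they were 64 and 341. With only the groups compared, the apices gave 28. The main fit gives each gene 1 spread over the 4 groups. The SD of replicate differences was 0.702 in younger apices and 0.387 in mature leaves, so the calls between the apices draw on the smaller spread of mature leaves. How far this and the loss of degrees of freedom account for the lower counts was not tested. Leaving out each array, whose partner then stands alone and is assumed to vary like the other groups, gave 27 to 1789, 95 to 1222, 466 to 3197 and 1403 to 3572 genes, 1483 to 5093 by the F test and 572 to 1069 in stage order. Of 136 list tests 35 passed, 32 with fry, which kept 13 of the 35 and lost 22, 0 with an estimated correlation, 39 with equal array medians and 33 to 41 without each array; the 4 comparisons had 11, 7, 7 and 10 calls. For named genes that passed, 3857 of the values under other settings stayed past the threshold in the same direction and 296 lost it, and without 1 array 1925 stayed and 627 lost it. No named gene that passed turned its direction, but some that had not passed did. ATHSP22.0 went to 0 in older against younger apices with equal medians, and turned there without Apex_5DAS replicate 2 (-0.17) and without Apex_14DAS replicate 1 (-0.34), and in expanding leaves against older apices without Apex_14DAS replicate 2 (-0.08). AT5MAT turned between the apices without Apex_14DAS replicate 1 (-0.27). The values of these genes without 1 array ran from -0.27 to 1.08 for AT5MAT, and up to 0.51 between the apices and 0.78 in expanding leaves against older apices for ATHSP22.0. GI turned in expanding leaves against older apices without Apex_14DAS replicate 2 (-0.28) or EL_14DAS replicate 1 (-0.36), and in mature against expanding leaves without the latter (0.24; lowest value -1.58, without EL_14DAS replicate 2). GUT2 turned between the apices without Apex_5DAS replicate 1 (0.02; lowest value -0.47), and in expanding leaves against older apices without Apex_14DAS replicate 1 (-0.01) or EL_14DAS replicate 1 (-0.12; highest value 0.14). OPS turned in mature against expanding leaves with quantile normalization (0.04), without EL_14DAS replicate 2 (0.38) and without ML_35DAS replicate 1 (0.15; lowest value -0.90). Signals near the pseudocount of 7.7 (2.94 on the log2 scale) carry little information on fold.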

Other observations

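The tests of the glucosinolate pattern, of the single array and the age difference for plastid transcripts, and of the array scaling for falling genes were chosen only after the results were seen; the reading of the mitochondrial, bright-gene and top-100 tests was narrowed after their values were seen.

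Some genes stood lower or higher in expanding leaves than in both older apices and mature leaves. There were 68 genes lower in expanding leaves than in both older apices and mature leaves and 31 genes higher than in both, where independent calls would give 23.8 and 40.5. The expanding-leaf arrays enter both comparisons and an error on them moves both, so these are not chance values and no excess is read from them. BCAT4, AOP3, GSTU20, AGL24, UGT74B1 and the fructose transporter SWEET17 were among the 68, and SWEET17 stood at 5.71 ± 0.50 in expanding leaves against 7.34 ± 0.29 in older apices and 7.34 ± 0.30 in mature leaves (SD, n = 2). The 31 included EXPA9, at 6.44 ± 0.19 against 5.11 ± 0.02 and 5.04 ± 0.02, the jasmonate-response factor ORA47 and TBL15. Younger apices did not enter this choice. Their means lay below those of expanding leaves for BCAT4 (4.58 against 4.77), AOP3 (7.16 against 7.61), GSTU20 (8.97 against 9.07) and UGT74B1 (7.24 against 7.47). For AGL24 and SWEET17 they lay above. TBL15 was also higher in younger apices (5.9 against 5.83), but EXPA9 and ORA47 were not. Rising at both steps were 59 genes and falling at both 111. Independent calls would give 19.4 and 49.7, which are not chance values either.

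Several enzyme families had no camera call between the ends of the series, and where fry gave a call it tested against no change and not against the other genes, whose median was -0.26. Of 23 serine carboxypeptidase-like genes, 3 rose and 8 fell, with scpl46 5.76-fold higher and scpl25 5.48-fold lower (relative median 0.20, camera adjusted p = 0.95, fry adjusted p = 0.041). Of 18 trichome birefringence-like genes, which act on wall polysaccharides, 1 rose and 6 fell, with TBL26 11.3-fold higher and TBL39 8.62-fold lower (relative median -0.08, camera adjusted p = 0.52, fry adjusted p = 0.0037). Of 28 glucosyltransferases 6 rose and 1 fell (camera adjusted p = 0.10, fry adjusted p = 0.21), and of 12 beta-glucosidases 2 rose and 3 fell (camera adjusted p = 0.52, fry adjusted p = 0.018). Of 9 U-box ubiquitin ligases none rose and 5 fell, led by PUB19, 8.47-fold lower (camera adjusted p = 0.35, fry adjusted p = 0.013). PUB19 changed by -3.77 and -2.43 without the Apex_5DAS replicates 1 and 2 and by -3.76 and -2.14 with the pseudocount at percentile 5 and 40, and TBL39 by -2.23 at percentile 40. TRY was 4.11-fold higher and SIM 3.11-fold lower in mature leaves.

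Plastid-encoded photosynthesis genes were lower in older than in younger apices. Without Apex_5DAS replicate 1 their relative median was -0.06, so that array carries the pattern. Less selection of polyadenylated RNA on that array might be a cause. The 3 measured mitochondrion-encoded genes had a median of 0.27 between the arrays and values from 0.03 to 1.79, beside 2.74 for the plastid genes. They are too few and too scattered to decide. The 25S ribosomal RNA signal was 193 on that array and 8.64 on replicate 2, but 1 control probe set does not decide it either. The difference between these 2 arrays was not confined to plastid-encoded genes. The lists of 9 and 25 nuclear photosynthesis genes had medians of 12.38 and 9.91 on Apex_5DAS replicate 1, against 11.78 and 9.66 on replicate 2. The medians of all genes were 6.24 and 6.43. A true difference between the ages stays open, since the lower of the younger-apex arrays lay 0.18 below the higher older-apex array (gap -0.18) and 1 array cannot settle it.

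Of 8 measured genes with a role in glucosinolate synthesis or transport, 5 (BCAT4, AOP3, GSTU20, UGT74B1 and AT2G31790) had both older apices and mature leaves more than 1 log2 unit above both younger apices and expanding leaves, and AOP1, GTR1 and GTR2 did not: GTR2 was at 7.58 in older apices and 7.48 in expanding leaves. The median contrast of the 8 genes (mean of the first pair of groups minus mean of the second) was 1.74 to 1.86 over 3 scalings. The lowest without 1 array was 1.48, without EL_14DAS replicate 2. So neither the scaling nor a single array removed the difference. But the set was followed only after its values were seen, and the scalings can move this contrast little. These values therefore describe its size and are not a test of the pattern. Harvest at different times of day could still be a cause: GI, the only clock gene followed, overlapped between these pairs of groups (gap -1.19), and it lay at 8.18 and 7.32 on the younger-apex arrays, at 6.97 and 5.31 on the older-apex arrays and at 7.60 and 5.78 on the expanding-leaf arrays, but at 5.98 and 6.05 on the mature-leaf arrays, and 1 gene does not settle it. Across all genes, 7 had every array of older apices and mature leaves more than 1 unit above every other array and none the reverse. For younger apices and mature leaves against the other groups, 3 genes were higher and 5 lower by this rule. For both apices against both leaves, 78 were higher and 22 lower. The count of 7 therefore does not set this split apart. A developmental difference among these tissues remains a hypothesis that was not tested.

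More genes fell than rose from expanding to mature leaves. The array scaling may account for this, as the share of falling genes was 35.3% with equal medians and 51.9% with quantile normalization. Dim genes near the pseudocount may contribute: the share was 60.1% among genes above the median intensity and 77.1% among the rest, but the first value lies too close to the bound of 60 set before to decide. After scaling, the percentile 30 value was 9.95 and 10.58 on the mature-leaf arrays, against 19.9 and 15.96 on the expanding-leaf arrays. The interquartile range of log2 values was 2.79 and 2.76 against 2.21 and 2.43. Multiplying each array by 1 factor does not remove such a difference. The 100 brightest probe sets held a larger share of the signal on the mature-leaf arrays than on any other array. The gap was 0.261 points to the next array, Apex_5DAS replicate 1 (13.8%). The share was 14% on both mature-leaf arrays, and 11.1% and 11.7% on the expanding-leaf arrays. But the trimmed mean leaves out the 454 brightest probe sets, so these do not enter the scaling and the test settles nothing. A true excess of falling genes in mature leaves stays open, as no value here fixes the total RNA per cell.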
